A study of Homo sapiens with 6 samples.

How the data were processed

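Chromatin from wild-type MRC5 lung fibroblasts was profiled by ChIP-seq with an antibody to NuMA (2 libraries) and with IgG (2 libraries), and 1 input library was sequenced for each arm. The submitters' processing notes name BWA 0.7.17-r1188, bedtools, featureCounts, MACS2 and the build hg38, without saying which made which file or how read pairs and reads in overlapping windows were handled. The deposited promoter table holds raw counts, whole numbers with no normalization, for 19957 windows that reach 1000 bp to each side of a TSS. The deposited metagene tables hold signal summed over genes, unscaled for depth, at 6000 positions around the TSS, 6000 around the termination site, and 1000 bins each for upstream flank, exons and downstream flank. Per the file headers the bins carry no size, and they are called positions here.

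Gene symbols were assigned by position, because the promoter table gives Ensembl identifiers only. A window took the symbol of the nearest protein-coding RefSeq gene whose 5' end lay within 1000 bp of its centre. This named 16251 windows (81.4%), with a median distance of 34 bp, and windows shifted by 20000 bp matched in 3.88% of cases. Symbols of closely spaced or duplicated genes are therefore less certain. Of all windows, 3741 (18.7%) overlap another, and 679 had no count in any library. Counts from 6 to 10 were even numbers in 72.7% to 79.8% of windows, against 60% for an even spread, so mates of a pair may have been counted separately and counting intervals may be too narrow. A count of 1 equals 0.925 to 2.73 CPM, depending on the library.

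Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with a minimum count of 10, TMM scaling, quasi-likelihood F-tests, Benjamini-Hochberg adjustment over all windows tested and a threshold of 0.05. NuMA ChIP against IgG ChIP used the 4 ChIP libraries. Each ChIP group against the mean of both inputs used all 6 libraries, where each input is a single library and is assumed to vary like the ChIP groups; each fit had 2 residual degrees of freedom. Standard errors were derived from the log2 fold change and the F statistic. Group means of CPM are given with SD. For groups at 0 the fold is taken against a floor of 3 counts over the group, and for 1 to 3 counts the ratio carries a 95% exact (Clopper-Pearson) interval. The floor takes the count of the other group as exact. The exact interval therefore starts at a smaller fold, which is given beside it. Metagene ratios were compared with an exact two-sided permutation test. The TSS ratio used 500 positions either side of the TSS over 2000 gene-body positions, flanks were the outermost 500 positions, and summits were found after averaging 51 positions. The whole-exon ratio instead used all upstream and downstream flank bins, which run up to the TSS. Exon ends were the first and last 100 of 1000 bins.

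The rule for named genes, the lists, the comparisons and most alternatives were written before the data were examined. For NuMA against IgG, the 10 largest changes in each direction were named among windows that passed with both NuMA libraries on the same side of both IgG libraries, passing over clone names and windows with identical counts. The highest and lowest member of each list, and NUMA1, TDP1, XRCC1, PARP1, FOS, JUN, EGR1 and POLR2A, were always named, as were the 5 largest changes in each direction against input. Other list members are given as examples. The 21 lists were immediate early response, single-strand break and base excision repair, double-strand break repair, mitotic spindle and NuMA partners, RNA polymerase II and pausing factors, cytosolic ribosomal proteins, replication-dependent histones, fibroblast and matrix, antioxidant defence, p53 targets, oxidative phosphorylation, mitochondrially encoded genes, small noncoding RNA genes, KRAB zinc fingers on chromosome 19, HOX and developmental regulators, olfactory receptors, germ cell genes, and markers of liver, neuron, blood and epithelial cells. Lists with at least 5 tested members were tested against all other windows with camera (limma 3.58.1, preset correlation 0.01, log2 CPM with a prior count of 2), adjusted over 19 lists, and again with an estimated correlation. In addition fry tested each list against no change, which is another question than the comparison with other windows.

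Alternatives were DESeq2 1.42.0 size factors and Wald test, limma-trend, total-count scaling, no count filter, at least 30 counts in each library of a group, each library left out in turn, counts thinned to the smallest total, a replicate block, own or pooled inputs, each ChIP group relative to its own input, a test above 1.5-fold, and other windows and denominators for the metagene ratios. Scaling on the metagene flanks, leaving out overlapping windows, leaving out each input and a window of 5 positions were added after the data were seen. The fits were tested on simulated data with the same dispersions, in which 100 windows changed 2-fold and 100 changed 4-fold. For NuMA against IgG, 2% of 2-fold and 58% of 4-fold changes were recovered, and 4.76% of calls were false. For NuMA against input the values were 7%, 69% and 3.80%, and for IgG against input 5%, 52% and 3.39%. The changed list was called in 1 of 1 and unchanged lists in 0 of 9 for each comparison. Simulated windows varied independently and the changed list held only raised windows. These list results therefore cannot show how the list test behaves when members are correlated, as in the real lists. In the simulation there were 63 calls for NuMA against IgG and 79 for NuMA against input, far fewer than in the data. Its adjusted threshold was therefore stricter, and its shares do not describe those real fits. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The newly made RNA and oxidative damage measurements of the wider study were not analysed here, and GC content was not used because no genome sequence was at hand.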

Results

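Chromatin immunoprecipitation with sequencing was carried out for NuMA, a large nuclear protein best known for organising the mitotic spindle poles, in MRC5 cells, a wild-type human lung fibroblast line. There were 6 libraries: 2 from NuMA ChIP, 2 from ChIP with non-specific IgG, 1 input library of the NuMA arm and 1 input library of the IgG arm. The deposited promoter counts cover 19957 windows that reach 1000 bp to each side of an annotated transcription start site (TSS) on build hg38. Total promoter counts were 1080879 and 664234 in NuMA ChIP replicates 1 and 2, 616242 and 366594 in IgG ChIP replicates 1 and 2, 729744 in the NuMA input and 791361 in the IgG input. A window held a median of 24 and 21 counts in the NuMA libraries, 27 and 18 in the IgG libraries, 36 in the NuMA input and 38 in the IgG input. The 1% of windows with the most counts held 7.67% and 5.44% of the NuMA counts, 3.73% and 3.31% of the IgG counts, and 3.03% and 3.2% of the input counts. Across windows, which are not independent replicates, Pearson's r was 0.925 between the NuMA libraries, 0.821 between the IgG libraries and 0.936 between the inputs. IgG replicate 1 was closer to the inputs (0.895 and 0.885) than to IgG replicate 2, whose r with the inputs was 0.770 and 0.784. These r values were taken on log2 of the count plus 1 over all 19957 windows, including 679 with no count in any library. In a separate calculation on log CPM of the ChIP libraries, r was 0.559 between the IgG libraries and 0.885 between the NuMA libraries. PCR reads are not independent molecules, so the intervals and floors given here cover counting error only. The labels do not say that the replicates came from separate cultures, so the p-values may measure only technical spread.

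The question behind the comparison of NuMA ChIP with IgG ChIP was where in the genome NuMA binds. The summed profile over genes describes signal at the level of gene regions only, and with 2 libraries per ChIP group it cannot settle binding. NuMA ChIP signal stood highest just downstream of the TSS. Signal within 500 positions of the TSS was 1.94 ± 0.23 times (SD, n = 2) that of the gene body in NuMA ChIP and 1.15 ± 0.15 times (SD, n = 2) in IgG ChIP, a ratio of 1.69. The inputs, with 1 library each, gave 1.33 and 1.36, so input chromatin itself was enriched near the TSS and the IgG mean lay below it. At its summit NuMA signal reached 2.51 ± 0.39 times the upstream flank (SD, n = 2) and IgG signal 1.32 ± 0.27 times (SD, n = 2), against 1.57 and 1.58 in the inputs. The summit lay 114 and 108 positions downstream of the TSS in the NuMA libraries, 105 and 96 in the IgG libraries, and 42 and 41 in the inputs. NuMA signal was raised on both sides of the TSS, at 1.86 ± 0.23 times the flank over the 500 positions upstream and 2.35 ± 0.34 times over the 500 downstream (SD, n = 2). IgG signal over the same stretches was 1.07 ± 0.14 and 1.26 ± 0.24 times the flank (SD, n = 2).

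**Figure D1:**
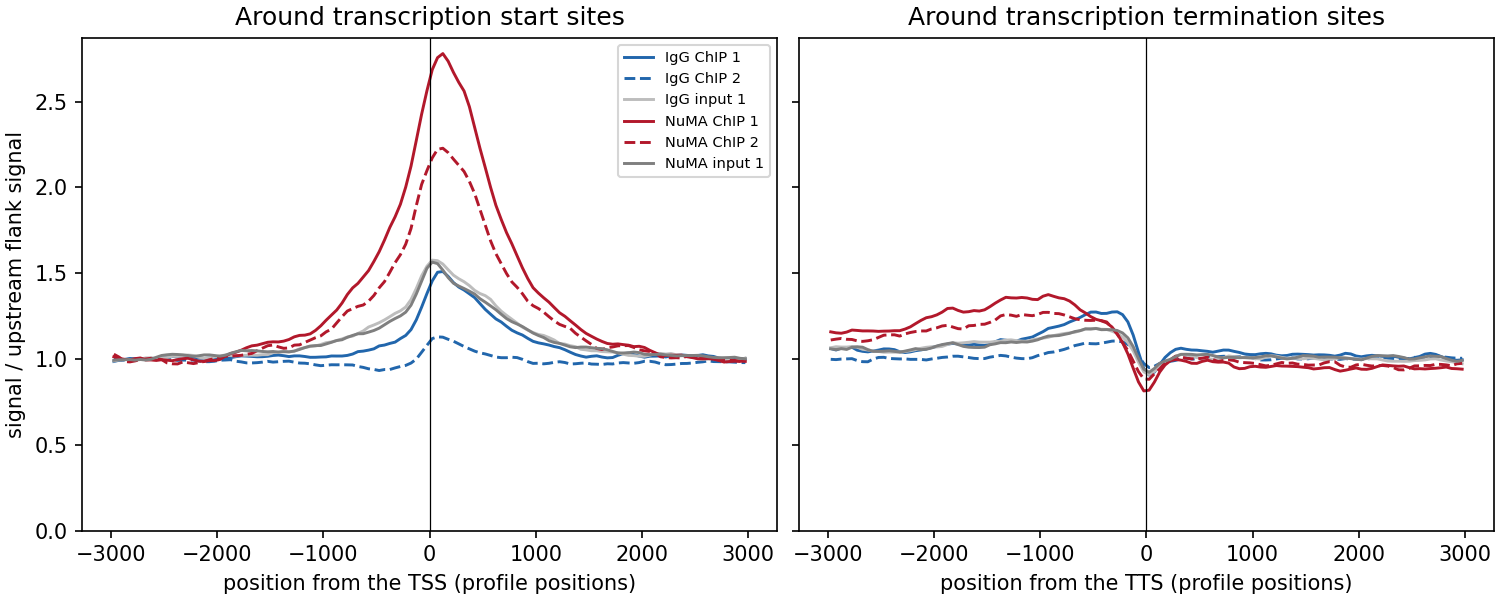
Signal summed over genes divided by the mean of the outermost 500 upstream positions (vertical axis, ratio) against position from the TSS or the termination site (horizontal axis, profile positions), 1 line per library. Both NuMA libraries rise near the TSS, to a group mean of 2.51 times the flank, and the inputs reach 1.57 and 1.58 times.

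Within exons, NuMA signal leaned to the 5' end: the first 100 exon bins held 1.90 ± 0.25 times the signal of the last 100 (SD, n = 2), against 1.17 ± 0.14 in IgG ChIP (SD, n = 2) and 1.30 and 1.33 in the inputs. Exons taken whole, over all upstream and downstream flank bins, stood at 1.142 ± 0.004 times the flanks in NuMA ChIP, 1.18 ± 0.09 in IgG ChIP (SD, n = 2) and 1.13 and 1.14 in the inputs. Those flank bins run up to the TSS, where NuMA signal was itself raised, so this ratio cannot show a lack of contrast. With only the outermost flank bins as denominator, NuMA ChIP lay above IgG ChIP. Around the transcription termination site, the 500 positions before it held 1.13 times the signal of the 500 after it in both ChIP groups. The summit there lay at positions -929 and -948 from the site in NuMA ChIP, -299 and -265 in IgG ChIP and -486 and -489 in the inputs. In each ratio that differed, both NuMA libraries lay above both IgG libraries. With 2 libraries against 2, the exact two-sided permutation test over 6 permutations cannot give a p below 0.333, and it gave 0.333 for the TSS, summit and 5' exon ratios and for the termination-site summit position, and 1 for the whole-exon and termination-site ratios.

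At single promoters, the windows higher in NuMA ChIP than in IgG ChIP included those of developmental regulators such as SIX2 and EN2 and of growth-response genes such as TRIB1 and JUN. Lower windows included those of the fibrinogen gene FGG, expressed in liver, and the T-cell receptor component CD3D, although markers of other cell types also rose, among them HBA1, SFTPD and GRIN1. Of 15727 windows tested, 2640 were higher, 3761 were lower and 9326 were not called. The median log2 fold change was 1.39 among higher windows and -2.05 among lower ones, and 188 windows were at least 4-fold higher while 1993 were at least 4-fold lower. These directions are relative to the other promoters, because libraries were scaled on promoter counts. Scaling on the signal far from the TSS instead moved the median of all windows by 1.30 (log2) and gave 7562 higher and 429 lower windows, so 94.6% of calls were higher in place of 41.2%. The promoter counts and the summed profile disagree between groups even near the TSS: counts per 1000 units of profile signal within 1000 positions were 13.3 and 12.2 in NuMA ChIP, 8.21 and 6.47 in IgG ChIP, and 10.3 and 10.8 in the NuMA and IgG inputs. Total counts over flank signal differed between NuMA and IgG ChIP by 0.81 (log2) through this disagreement and by a further 0.69 through profile signal near the TSS over the flanks. Scaling on total counts moved the median by -0.16.

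Leaving out NuMA replicate 1 gave 596 higher and 1445 lower windows, leaving out IgG replicate 2 gave 1050 and 1914, and leaving out IgG replicate 1 gave 2320 and 2337. In a DESeq2 test there were 1634 higher and 2117 lower windows, a minimum of 30 counts per library gave 772 and 1819, requiring a change above 1.5-fold gave 1366 higher, and taking each ChIP group relative to its own input gave 199 and 405.

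**Figure D2:**
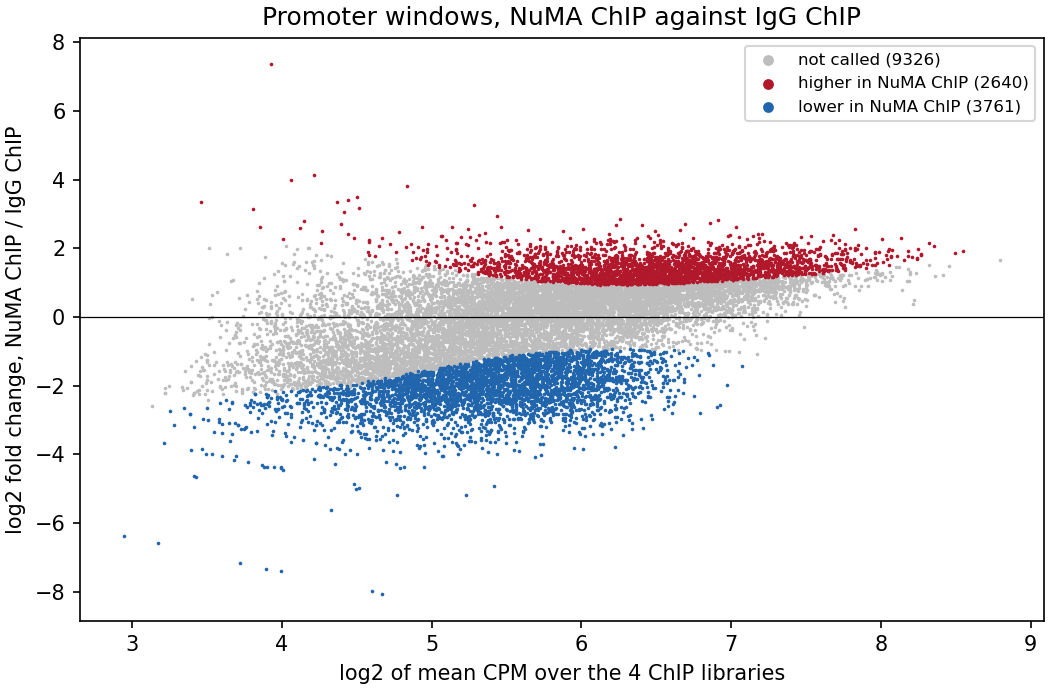
Each point is 1 of 15727 promoter windows, with the log2 of the mean normalised read count (CPM) over the 4 ChIP libraries on the horizontal axis and the log2 fold change of NuMA ChIP over IgG ChIP on the vertical axis. The 2640 higher and 3761 lower windows are coloured, and lower windows reach larger changes than higher ones; scaling on the profile flanks instead gives 7562 higher and 429 lower.

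Among the named genes with the largest increases, GYG2, which encodes the glycogen primer glycogenin 2 (X, 2827787 to 2829787), rose by a log2 fold change of 2.85 ± 0.47 (SE, adjusted p = 3.89e-06), from 17.9 ± 6.84 to 135 ± 78.3 CPM (SD, n = 2 each). SEPHS1, a selenophosphate synthetase homologue (10, 13347299 to 13349299), rose by 2.95 ± 0.57 (SE, adjusted p = 4.73e-05). ABHD15 (17, 29566138 to 29568138) rose by 3.26 ± 0.63 (SE, adjusted p = 5.79e-05), PPFIA3 by 3.34 ± 0.93, SPTBN4, a spectrin gene, by 3.17 ± 0.88 and POLR1D, a subunit of RNA polymerases I and III, by 3.06 ± 0.90. IgG replicate 2 had 0 counts in these last 4 windows, and without IgG replicate 1 the fitted values were 8.64, 7.74, 7.87 and 7.76, which set no bound. Without IgG replicate 2 these 4 still passed, at 2.39 to 2.69. GYG2 was at 3.59 without IgG replicate 1 and 2.13 without NuMA replicate 1. A further 4 genes had at most 3 IgG counts, so their folds are count ratios with 95% exact counting intervals. PABPC1L2B, with 60 NuMA and 2 IgG counts, was 19.3-fold higher (5.12 to 163), FBXO36 16.8-fold (4.41 to 142), PWP2 10.9-fold (2.81 to 94.1) and PKP4 9.23-fold (2.96 to 46.5). PABPC1L2B has a near-identical neighbouring copy, and the windows of ABHD15, PPFIA3, SPTBN4, POLR1D, FBXO36 and PKP4 overlap another window by 914 to 1792 bp. Against input, NuMA ChIP passed at GYG2 (1.97), SEPHS1 (1.23) and SPTBN4 (3.02). It did not pass at FBXO36 (0.51), ABHD15 (1.05), PWP2 (1.51), POLR1D (1.78), PPFIA3 (1.81), PABPC1L2B (2.31) or PKP4 (3.01), with adjusted p = 0.0757 to 0.673. IgG ChIP lay below input in all of these windows, from -3.6 at FBXO36 to -0.31 at PKP4, none passing. Without NuMA replicate 1, SEPHS1 (2.55, adjusted p = 0.0729), PPFIA3 (0.15), SPTBN4 (0.0828), POLR1D (0.176), PABPC1L2B (0.173), FBXO36 (0.127) and PKP4 (0.32) did not pass. SPTBN4 (0.0754), PWP2 (0.121) and PKP4 (0.0832) did not pass without NuMA replicate 2, and PWP2 (0.175) and PKP4 (0.129) without IgG replicate 2.

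The largest decreases were windows with no NuMA count. LAMB3, a laminin chain of epithelial basement membranes (1, 209651467 to 209653467), had 0 NuMA counts against 50 IgG counts. It was 25.9-fold lower on a floor of 3 counts over the group, with a 95% exact counting interval from 20.3-fold. On the same floor, with the start of that interval in brackets, the odorant receptor gene OR13C9 was 22.8-fold lower (17.75). The DNA glycosylase gene MUTYH and the gene HSFX3 were each 16.6-fold lower (12.7). The keratin gene KRT40 was 15-fold lower (11.4), the pepsinogen gene PGA4 9.31-fold (6.82) and GOLGA8K 8.28-fold (5.99). AADAC, an arylacetamide deacetylase of liver, had 1 NuMA count against 38 and was 59.0-fold lower (95% exact counting interval 9.97 to 2390). CLDN24 was 44.2-fold lower (11.7 to 374) and ARR3, a cone photoreceptor arrestin, 31.8-fold lower (8.27 to 272). OR13C9, HSFX3, PGA4 and GOLGA8K belong to families of similar copies, where reads are hard to place, and the MUTYH window overlaps another by 1199 bp. Against input, NuMA ChIP did not pass at OR13C9 (adjusted p = 0.0733), HSFX3 (0.073), PGA4 (0.126) or GOLGA8K (0.166). IgG ChIP lay above input in those windows, at 3.12, 2.25, 1.43 and 1.43, none passing. NuMA ChIP was lower than input at LAMB3, MUTYH, KRT40, AADAC, CLDN24 and ARR3. KRT40 (adjusted p = 0.0608), PGA4 (0.146) and GOLGA8K (0.182) did not pass without NuMA replicate 1, PGA4 (0.0721) and GOLGA8K (0.098) without NuMA replicate 2, and ARR3 (0.0825) without IgG replicate 2.

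Of 49 named genes that passed in this comparison, 12 passed under each of the up to 10 alternatives run for single genes and 37 lost the call in at least 1. Leaving out NuMA replicate 1 ended 27 of 48 calls, IgG replicate 2 ended 17 of 47, NuMA replicate 2 ended 13 of 49 and IgG replicate 1 ended 9 of 43. Flank scaling ended 13 of 49 and the DESeq2 test 12 of 49. GYG2, ABHD15, LAMB3, OR13C9, MUTYH, HSFX3, AADAC, CLDN24, TRIB1, SIX2, JUN and OR10A4 were the 12. The single-gene alternatives did not include, among others, a minimum of 30 counts, the test above 1.5-fold or values relative to own inputs. Against input, NuMA ChIP did not pass at ABHD15 (adjusted p = 0.0757), OR13C9 (0.0733), HSFX3 (0.073) or JUN (-0.05, 0.944). It passed at the others of the 12. IgG ChIP lay below input at JUN (-2.11, adjusted p = 0.0182), a call that ended without IgG replicate 2. Alternatives that gave no result for a gene are not counted, and MUTYH had 8 with a result and ABHD15, HSFX3 and CLDN24 had 9.

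The gene lists fixed before the data were examined separated into groups. Promoters of HOX and other developmental regulators were higher as a group, with 13 of 33 tested members rising, 1 falling and 19 not passing, and a median of 0.91 (1.88-fold). The call was lost with an estimated correlation, and HOX genes taken alone as a family did not pass, as given further below. SIX2, a homeobox regulator of kidney progenitors (2, 45008431 to 45010431), rose by 2.03 ± 0.45 (SE), from 38.8 ± 18 to 165 ± 51.9 CPM (SD, n = 2 each). HOXD8 rose by 1.53, EN2 by 1.69 and NKX2-1, a lung and thyroid regulator, by 1.56, while GATA4 changed by -1.63. GATA4 did not pass without IgG replicate 1 (-0.90, adjusted p = 0.258), without NuMA replicate 1 (-1.13, 0.147), in the DESeq2 test (0.0577) or on flank scaling (-0.39, 0.58). Against input GATA4 did not pass (-0.68, adjusted p = 0.258). SIX2 was at 2.88 without IgG replicate 1. The list test gave adjusted p = 0.00049, but adjusted p = 0.709 with an estimated correlation. Immediate early genes, which respond within minutes to growth signals or stress, were also higher as a group. Of 28 tested, 8 rose, 2 fell and 18 did not pass, with a median of 0.71 (1.63-fold). TRIB1, a pseudokinase gene (8, 125429320 to 125431320), rose by 2.15 ± 0.45 (SE, adjusted p = 0.00015). JUN, a subunit of the AP-1 factor (1, 58783328 to 58785328), rose by 1.92 ± 0.46 (SE, adjusted p = 0.000938) and JUND by 1.53, with JUN at 2.91 without IgG replicate 1, whereas ATF3 fell by 2.54 and FOSB by 1.41. ATF3 had 16 and 0 NuMA counts and did not pass against input (-1.40, adjusted p = 0.123). It did not pass without IgG replicate 2 (adjusted p = 0.137), without NuMA replicate 2 (-1.61, 0.082), in the DESeq2 test (0.371) or on flank scaling (-1.15, 0.164), and its fit of -7.97 without NuMA replicate 1 is against 0 counts and sets no bound. FOS had a log2 fold change of -0.08 ± 0.42 (SE, adjusted p = 0.891) and EGR1 of 0.82 ± 0.40 (SE, adjusted p = 0.0852). The list's adjusted p was 0.00478, and adjusted p = 0.576 with an estimated correlation. Adjusted over the list alone, the counts were 13 and 1 for the developmental list and 8 and 2 for the immediate early list. On flank scaling 26 developmental promoters were higher and none lower (median 2.22), and 22 immediate early promoters were higher and none lower (median 2.01).

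The 5 lists that were lower as groups hold markers of liver and blood, germ cell genes, olfactory receptors and zinc finger genes. Liver marker promoters fell in 10 of 15 tested, with a median of -2.03, and among them were FGG, 24.1-fold lower (95% exact counting interval 6.12 to 208), and AHSG, a secreted liver glycoprotein, at -3.82. Germ cell genes fell in 11 of 17, median -1.67, among them the cancer-testis gene MAGEC1 at -3.10 ± 0.93 (SE). Olfactory receptor genes fell in 6 of 10, median -1.84, with OR10A4 (11, 6875624 to 6877624) at -3.31 ± 0.61 (SE). Blood cell markers fell in 8 of 18 and rose in 1, median -1.54, with CD3D at -3.64 ± 0.93 and the alpha globin gene HBA1 at 1.27 ± 0.41 (SE). KRAB zinc finger genes on chromosome 19, which encode repressors of transposable elements, fell in 11 of 29, median -1.08, with ZNF714 at -2.38 ± 0.49 (SE). The highest members of 4 of these lists did not pass: ZNF347 at 0.85 (adjusted p = 0.105), APOB at 0.53 (0.293), SYCP3 at 0.36 (0.482) and OR1J4 at -0.77 (0.406). FGG did not pass without NuMA replicate 2 (adjusted p = 0.0753), CD3D without IgG replicate 1 (-3.31, 0.0546), and HBA1 without IgG replicate 2 (1.17, 0.0692) or NuMA replicate 1 (0.81, 0.316). MAGEC1 did not pass without IgG replicate 1 (-2.96, adjusted p = 0.0751), IgG replicate 2 (-2.94, 0.102) or NuMA replicate 1 (-2.48, 0.191), and was at -3.84 without NuMA replicate 2. CD3D was at -4.55 without NuMA replicate 1 and ZNF714 at -3.05 without NuMA replicate 2. On flank scaling ZNF714 (-1.07, adjusted p = 0.111) and MAGEC1 (-1.82, 0.0836) did not pass. Against input FGG did not pass (adjusted p = 0.123), while CD3D (0.0271), MAGEC1 (0.036), OR10A4 (0.0188) and ZNF714 (0.0228) were lower in NuMA ChIP. Adjusted p was 0.00049 for liver and for germ cell genes, 0.00401 for olfactory receptors and 0.00929 for blood and for zinc finger genes. Each call was lost when the correlation was estimated: adjusted p = 0.551 with an estimated correlation for liver, germ cell and blood lists and 0.576 for the other lists. Adjusted over the list alone, 8 olfactory receptor genes and 10 blood markers were lower, and the other counts did not change. Scaled on the profile flanks, the median of the zinc finger list turned to 0.18, while liver stayed at -0.82, olfactory receptors at -0.50, germ cell genes at -0.39 and blood markers at -0.27. That scaling moves all windows by 1.30. Relative to the median of all windows, the lists stood at -1.04 and -1.08 for zinc finger genes, -1.99 and -2.07 for liver, -1.79 and -1.76 for olfactory receptors, -1.62 and -1.65 for germ cell genes and -1.50 and -1.52 for blood markers, without and with it. The zinc finger call did not hold on flank scaling (adjusted p = 0.0535) or without IgG replicate 1 (0.103), and the other 4 calls held in both. On that scaling few members were called: 4 zinc finger genes higher and 0 lower, liver markers 1 and 3, olfactory receptors 0 and 1, germ cell genes 1 and 2 and blood markers 3 and 3.

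**Figure D3:**
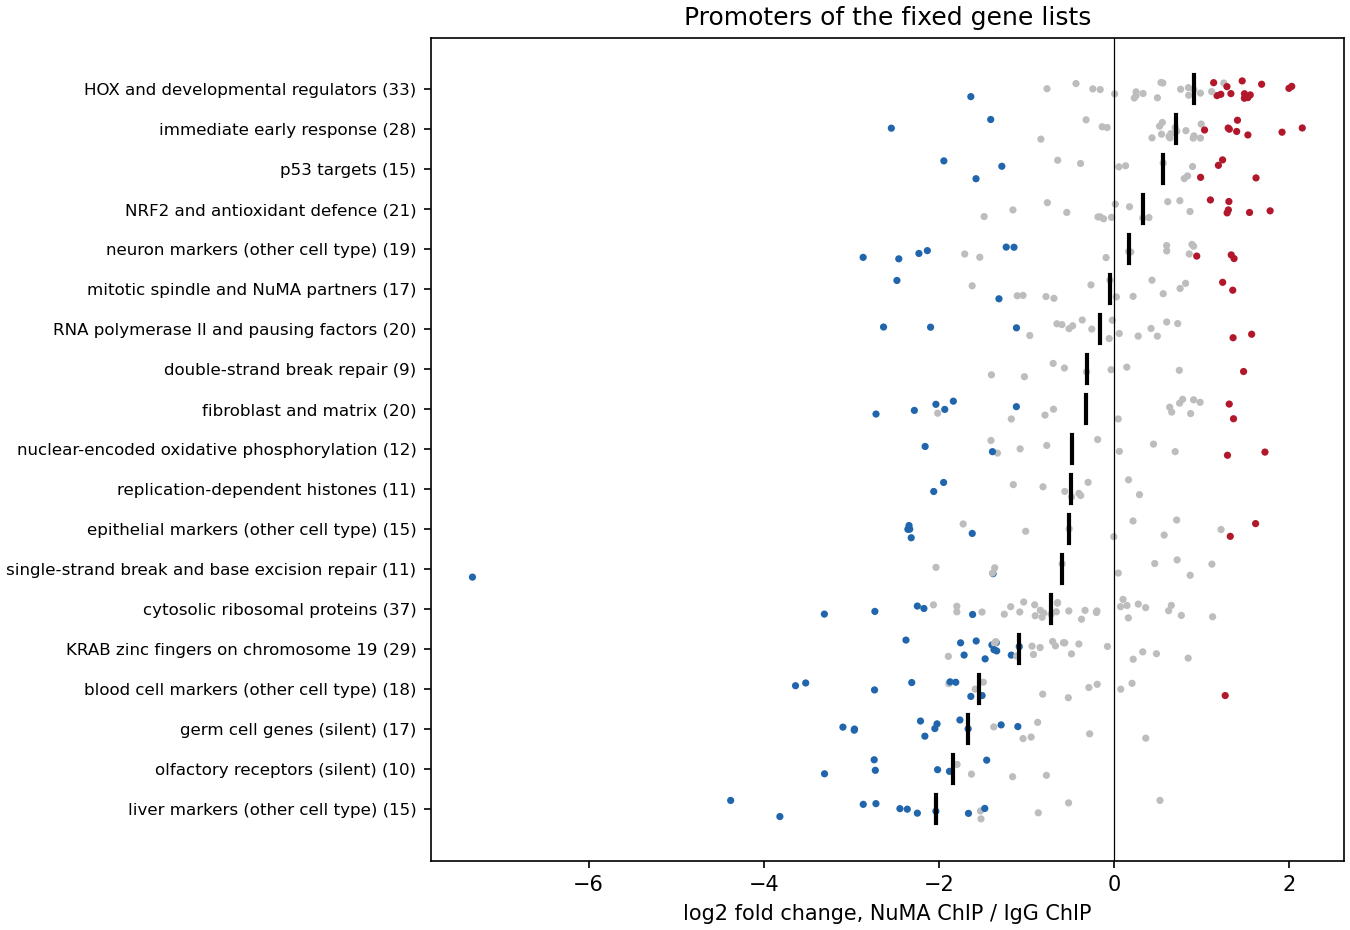
Log2 fold change of NuMA ChIP over IgG ChIP (horizontal axis) for each tested promoter of 19 fixed lists, with the number tested in brackets, red for higher, blue for lower, grey for not called and a black bar at the median. Medians run from -2.03 for liver markers to 0.91 for developmental regulators, and on flank scaling these become -0.82 and 2.22.

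The other 12 tested lists did not pass as groups, and on flank scaling, which moves all windows by 1.30, all 12 medians were positive. Members called higher and lower on that scaling were 9 and 0 for ribosomal proteins, and 10 and 0 each for fibroblast genes and p53 targets. They were 13 and 0 for antioxidant defence, 9 and 0 for neuron and 7 and 0 for epithelial markers, and 0 and 0 for histones. Spindle and RNA polymerase II lists had 8 and 0 each, oxidative phosphorylation 5 and 0, single-strand break repair 5 and 1, and double-strand break repair 3 and 0. Their counts adjusted over the list alone were the same except where given. In antioxidant defence, 6 of 21 promoters rose and none fell, among them the lipid peroxidase gene GPX4 at 1.78 ± 0.42 (SE) and the ferritin gene FTH1 at 1.55, with a median of 0.33 (adjusted p = 0.13). The lowest member, PRDX3, was at -1.48 and did not pass (adjusted p = 0.114). Among p53 targets 4 of 15 rose and 3 fell, with MDM2, the ligase that degrades p53, at 1.62 ± 0.48 and the cell cycle inhibitor CDKN1A at -1.94 ± 0.75 (SE), median 0.56 (adjusted p = 0.427). Cytosolic ribosomal protein promoters fell in 5 of 37, or 4 adjusted over the list alone, with RPL32 at -3.31 ± 1.04 (SE). Their median was -0.72 (adjusted p = 0.0956) and turned to 0.61 on flank scaling. The highest member, RPL13, was at 1.13 and did not pass (adjusted p = 0.0621). RPL32 had 0 and 4 NuMA counts. It did not pass without IgG replicate 1 (-3.24, adjusted p = 0.0766), IgG replicate 2 (-3.06, 0.151) or NuMA replicate 1 (-2.17, 0.318) or on flank scaling (-2.04, 0.0812), and its fit of -7.17 without NuMA replicate 2 is against 0 counts and sets no bound. Fibroblast and matrix genes split, with COL6A1 at 1.32 and COL6A2 at 1.37 higher and 6 of 20 lower, among them THY1 at -2.72 ± 0.66 (SE) and SPARC at -2.28; the median was -0.32 (adjusted p = 0.832). Histone genes fell in 2 of 11 and in 0 adjusted over the list alone, with H1-3 at -2.06 ± 0.76 (SE), H1-4 highest at 0.29 without passing (adjusted p = 0.791), and a median of -0.49 (adjusted p = 0.363). On flank scaling THY1 (-1.37, adjusted p = 0.0829) and H1-3 (-0.735, 0.425) did not pass. Against input GPX4 (0.53, adjusted p = 0.346) and MDM2 (0.37, 0.531) did not pass, while COL6A2 did (1.595, 0.00679). Of the lower genes, THY1 (-1.17, 0.204) and CDKN1A (-1.475, 0.103) did not pass against input, while RPL32 (3.48e-07) and H1-3 (0.00757) did. H1-3 did not pass when any of the 4 libraries was left out (-2.19 to -1.82, adjusted p = 0.115 to 0.178). CDKN1A did not pass without IgG replicate 1 (-1.21, adjusted p = 0.421), NuMA replicate 1 (-1.95, 0.191) or NuMA replicate 2 (-1.87, 0.12), in the DESeq2 test (0.0889) or on flank scaling (-0.72, 0.426). GPX4 did not pass without NuMA replicate 1 (adjusted p = 0.066), MDM2 without NuMA replicate 2 (1.23, 0.178) and THY1 without IgG replicate 2 (adjusted p = 0.0567). COL6A2 was at 2.12 without IgG replicate 1 and did not pass without IgG replicate 2 (1.08, 0.244) or NuMA replicate 1 (1.23, 0.0685).

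For the spindle and NuMA partner list, the microtubule polymerase gene CKAP5 at 1.36 ± 0.49 (SE) and PAFAH1B1 at 1.24 were higher, and the mitotic kinase gene AURKB at -2.48 ± 0.70 (SE) and TPX2 at -1.31 were lower, out of 17 tested (median -0.05, adjusted p = 1). In the RNA polymerase II and pausing list, the elongation kinase gene CDK9 rose by 1.57 ± 0.41 (SE) and NELFB by 1.36, and CDK7, SUPT4H1 and SUPT16H, at -2.63 ± 0.80 (SE), were lower out of 20, with 2 higher and 1 lower adjusted over the list alone (median -0.15, adjusted p = 1). Of 11 single-strand break and base excision repair genes tested, the oxidised-guanine repair genes MUTYH and OGG1 were lower, OGG1 at -1.38, and the median was -0.59 (adjusted p = 0.607), with MPG highest at 1.12 (adjusted p = 0.189). PARP1, a sensor of strand breaks, had 0.87 ± 0.48 (SE, adjusted p = 0.128). Of 9 double-strand break repair genes only H2AX, at 1.48 ± 0.46 (SE), passed, MDC1 was lowest at -1.40 (adjusted p = 0.14), and the median was -0.31 (adjusted p = 1). Oxidative phosphorylation genes had 2 of 12 higher and 2 lower, among them COX5A at 1.73 ± 0.57 and UQCRC2 at -2.16 ± 0.85 (SE), median -0.48 (adjusted p = 0.832). Epithelial markers had 2 of 15 higher, or 3 adjusted over the list alone, and 5 lower, with the surfactant gene SFTPD at 1.62 ± 0.54 and CLDN18 at -2.35 ± 0.70 (SE), median -0.51 (adjusted p = 0.636). Neuron markers had 3 of 19 higher and 6 lower, with the glutamate receptor gene GRIN1 at 1.37 ± 0.45 and GAD1 at -2.86 ± 0.70 (SE). Their median was 0.17, while the mean of -0.39 and the test's direction were negative (adjusted p = 1), and total-count scaling turned the median to -0.01. Without NuMA replicate 1, CKAP5 (adjusted p = 0.171), AURKB (0.0919), CDK9 (1.29, 0.0869), SUPT16H (0.125), H2AX (1.02, 0.35), SFTPD (0.91, 0.174), CLDN18 (0.0898) and GRIN1 (1.39, 0.0506) did not pass. Without IgG replicate 2, CKAP5 (0.0867), AURKB (0.0516), SUPT16H (0.12), SFTPD (1.44, 0.203), CLDN18 (0.0665) and GRIN1 (0.91, 0.264) did not pass. Without IgG replicate 1, SFTPD (2.13, 0.0695) and CLDN18 (0.0544) did not, and without NuMA replicate 2 neither did CKAP5 (0.105) or COX5A (1.19, 0.32). UQCRC2 did not pass when any of the 4 libraries was left out (-2.38 to -1.52, adjusted p = 0.0805 to 0.396). CDK9 was at 2.21 and GRIN1 at 2.64 without IgG replicate 1, and GAD1 at -3.64 without NuMA replicate 1. On flank scaling GAD1 (-1.54, adjusted p = 0.0594), AURKB (-1.17, 0.155), SUPT16H (-1.31, 0.155), CLDN18 (-1.04, 0.211) and UQCRC2 (-0.79, 0.436) did not pass. Against input CKAP5 (0.35, adjusted p = 0.574), CDK9 (0.51, 0.364), H2AX (0.0778), COX5A (0.111) and GRIN1 (0.25) did not pass, while SFTPD did (0.000374). Of the lower genes, GAD1 (-1.44, 0.127) did not pass against input, while AURKB (0.00021), SUPT16H (7.07e-06), CLDN18 (0.0441) and UQCRC2 (0.000346) did.

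The promoters of NUMA1, TDP1 and POLR2A held too few counts for a test against IgG. NUMA1 itself had 1 NuMA count against 9 IgG counts in a window that overlaps another by 1637 bp, a 14.0-fold lower ratio with a 95% exact counting interval of 1.94 to 612, and was not tested. TDP1, a repair phosphodiesterase, had 13 NuMA counts and 0 IgG counts, in a window that shares 1841 bp with another. It was 2.79-fold higher on a floor of 3 counts over the group (95% exact counting interval from 1.96-fold). Against input TDP1 did not pass, at -0.61 ± 1.53 (SE, adjusted p = 0.799). POLR2A had 0 and 3 counts, which allows no fold, and XRCC1 was not matched by position. Of the 2 lists without a matched member, mitochondrially encoded genes and small noncoding RNA genes, no value was obtained.

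**Figure D4:**
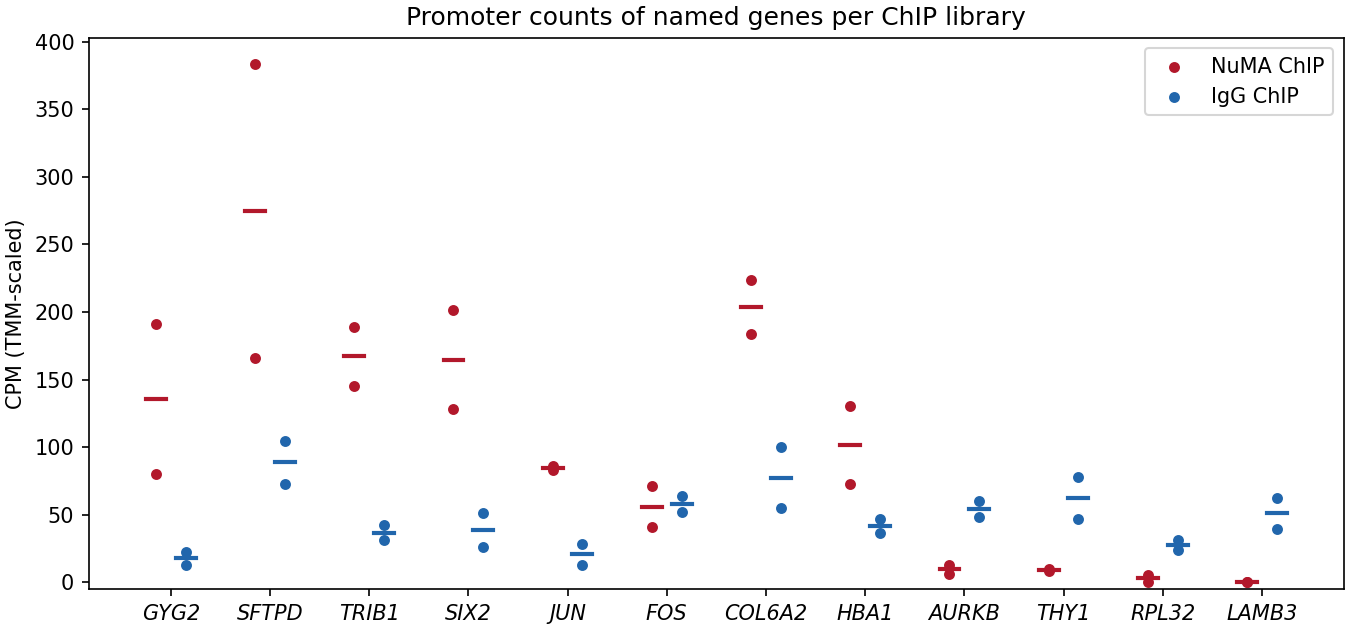
TMM-scaled read count (CPM, vertical axis) for 12 of the named promoters (horizontal axis) in each NuMA ChIP library (red) and IgG ChIP library (blue), with bars at the group means (n = 2). JUN reads 84.4 against 20.9 CPM, FOS 56.0 against 57.9 and LAMB3 0 CPM in both NuMA libraries.

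Against input, which shows how sheared chromatin itself was recovered, developmental regulators again stood out in NuMA ChIP. Of 34 tested, 21 promoters rose and none fell, with a median of 1.23 (2.34-fold), among them SOX1 at 2.88, NKX2-1 at 2.44, HOXD1 at 2.38 and EN2 at 2.37. Ribosomal protein promoters were lower, 16 of 39 with a median of -1.08, among them RPL32 at -4.57 ± 0.74 (SE) and RPS27 at -3.04. Histone promoters fell in 4 of 17, median -1.51, and liver markers fell in 5 of 16 and rose in 1, median -1.16. The histone call did not hold without overlapping windows (adjusted p = 0.0563), where 10 of the 17 overlap another, or without NuMA replicate 1 (0.0766), and the liver call did not hold with no count filter (0.0711). For developmental regulators, ribosomal proteins, histones and liver markers, adjusted p was 3.54e-06, 2.96e-05, 0.00109 and 0.014, and in all 4 lists adjusted p = 0.573 with an estimated correlation. Adjusted over the list alone, the counts were 22 higher for developmental regulators, 17 lower for ribosomal proteins, 4 lower for histones, and 6 lower and 1 higher for liver markers. On flank scaling they were 8 higher for developmental regulators, 8 lower for ribosomal proteins, 4 lower for histones and 3 lower for liver markers, with none the other way. No immediate early promoter was called on that scaling. The remaining 15 lists did not pass, among them immediate early genes, of which 3 of 28 rose and 2 fell (median 0.48, adjusted p = 0.27). JUN had a log2 fold change of -0.05 ± 0.40 (SE, adjusted p = 0.944) against input, whereas TRIB1 rose by 1.32 ± 0.44 (SE, adjusted p = 0.0135) and SIX2 by 1.46 ± 0.44 (SE, adjusted p = 0.00579). For p53 targets the median was 0.002 and the mean -0.17, with a negative test direction.

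Over all 17226 windows tested, 2960 were higher and 2045 lower in NuMA ChIP than in input, or 59.1% of calls higher. Scaling on total counts moved the median by -0.44 and gave 1852 higher and 3313 lower (35.9% higher), and scaling on the profile flanks moved it by 0.30 and gave 1861 and 684 (73.1% higher). On a floor of 3 counts over the group, LAMB3 was 28.5-fold lower, with 0 NuMA counts against 103 input counts. On that floor SLC25A53 was 13.5-fold lower, MUTYH 12.2-fold, SRGAP2, which also had 0 IgG counts, 9.39-fold, and KRT40 7.74-fold. In the same order, the 95% exact counting intervals started at 22.7-, 10.6-, 9.48-, 7.23- and 5.885-fold. The largest increases had at most 3 input counts: SLCO1B1, a liver anion transporter, was 25.3-fold higher (95% exact counting interval 4.08 to 1048), PDE3B 23.7-fold (7.73 to 118), CASP5 15.1-fold (3.76 to 131), OR8K1 14.5-fold (3.60 to 126) and RHAG 10.9-fold (2.60 to 96.5). IgG ChIP against input had log2 fold changes of 5.95 at SLCO1B1, 5.40 at OR8K1, 5.24 at CASP5 and 5.95 at RHAG. Those of NuMA ChIP were smaller, at 4.99, 4.78, 4.71 and 4.30, while PDE3B had 2.79 in IgG and 4.48 in NuMA ChIP. IgG against input did not pass in these 5 windows (adjusted p = 0.0543 to 0.261). In 4 of them IgG counts came mostly from replicate 2, with 2 and 24 counts in replicates 1 and 2 at SLCO1B1, 2 and 22 at OR8K1, 0 and 21 at CASP5 and 0 and 34 at RHAG, while PDE3B had 9 and 4. Against IgG, NuMA ChIP had -1.18 at SLCO1B1 (adjusted p = 0.248), -0.85 at OR8K1 (0.412) and 1.53 at PDE3B (0.0905), none passing. Among the 10 genes named against input, the replicate block ended 5 calls and total-count scaling 4. The DESeq2 test gave a result for only 1 of the 10, and MUTYH had results under 8 alternatives. An alternative without a result is not counted as a lost call. Of these 10 genes, LAMB3 and MUTYH passed under every alternative run for them, and leaving out NuMA replicate 1 ended the other 8 calls. Without NuMA replicate 2, SLCO1B1 (adjusted p = 0.167), OR8K1 (0.227), CASP5 (0.0829), RHAG (0.118), SRGAP2 (0.195) and KRT40 (0.0672) did not pass. Without NuMA replicate 1 there were 1365 higher and 956 lower windows, without the IgG input 1334 and 1863, without the NuMA input 1246 and 1100, and without IgG replicate 1 there were 1959 higher. DESeq2 gave 1876 and 619, the NuMA input alone 1865 and 1314, pooled inputs 3427 lower, and a minimum of 30 counts 3232 lower.

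The IgG libraries, compared with input to measure the background, differed at few single promoters but shifted by gene class. Olfactory receptors, germ cell genes, blood and liver markers and zinc finger genes were higher in IgG. With adjusted p in brackets, olfactory receptors had a median of 1.06 (0.00387), germ cell genes 0.83 (0.000271), blood markers 0.71 (0.00887), zinc finger genes 0.65 (0.0429) and liver markers 0.64 (0.00887), none of which held with an estimated correlation. The olfactory receptor call did not hold without IgG replicate 2 (adjusted p = 0.0895) or with a replicate block (0.0711), nor did the zinc finger call without IgG replicate 1 (0.331), with the block (0.104) or without overlapping windows (0.0558). On flank scaling the last 4 of these turned, to -0.01, -0.12, -0.18 and -0.18, and the olfactory receptor median was 0.15. That scaling moves all windows by -0.83, and relative to all windows these 4 lists stood at 0.70, 0.58, 0.52 and 0.50 without it and 0.70, 0.58, 0.53 and 0.52 with it. With it zinc finger genes (adjusted p = 0.19) and single-strand break repair genes (0.0663) did not pass. Neuron markers, at 0.62 (0.0771), epithelial markers, at 0.40 (0.595), and double-strand break repair genes, at -0.39 (0.197), did not pass. Housekeeping and stress-response lists were lower, with oxidative phosphorylation at -0.62 (0.00887), RNA polymerase II factors at -0.61 (0.000271), antioxidant defence at -0.57 (0.000271), histones at -0.51 (0.00887), ribosomal proteins at -0.48 (6.67e-05) and p53 targets at -0.46 (0.00379). Immediate early genes had -0.43 (0.00016), spindle genes -0.39 (0.00364) and single-strand break repair genes -0.29 (0.0394). Of these, single-strand break repair and oxidative phosphorylation did not hold without IgG replicate 1 (adjusted p = 0.134 each) or with no count filter (0.41 and 0.0649), and histones did not hold without overlapping windows (0.144). None of these 14 calls held with an estimated correlation (smallest adjusted p = 0.315 with an estimated correlation). Adjusted over the list alone, 6 zinc finger, 4 olfactory receptor, 2 germ cell, 1 blood marker and 1 neuron marker promoters were higher, and 3 antioxidant, 1 p53 target, 1 immediate early and 1 RNA polymerase II promoters were lower. Developmental regulators had a median of 0.47, which turned to -0.37 on flank scaling, and did not pass (adjusted p = 0.116). Fibroblast genes had a median of -0.23, a mean of 0.05 and a negative test direction.

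At single promoters, 41 were higher and 11 lower in IgG than in input by edgeR. TRIM51 rose by 5.59 ± 1.39, KRTAP9-1 by 3.73 ± 0.86, RUNX2, the regulator of bone formation, by 3.72 ± 0.82, KRTAP19-3 by 2.69 ± 0.69 and the hormone subunit gene CGA by 2.65 ± 0.69 (SE). The endoplasmic reticulum chaperone gene HSP90B1 fell by 2.78 ± 0.58, MYL12B by 2.24 ± 0.58, CITED2 by 2.23 ± 0.49, CCAR1 by 2.11 ± 0.52 and JUN by 2.11 ± 0.47 (SE, adjusted p = 0.0182). All 10 calls ended without IgG replicate 2, with total-count scaling and in DESeq2. Without IgG replicate 2 the values were, in the same order, 3.88, 3.91, 2.04, 2.05 and 2.29, and -2.62, -1.73, -1.77, -2.72 and -1.66. Without IgG replicate 1, TRIM51 was at 6.43, RUNX2 at 4.53, MYL12B at -3.43, CITED2 at -3.17 and JUN at -2.98, and CCAR1 did not pass (-1.56, adjusted p = 0.19). TRIM51 (0.0618) and MYL12B (0.0556) did not pass without NuMA replicate 1, nor KRTAP9-1 (0.0575), KRTAP19-3 (0.0562) and CGA (0.0607) without NuMA replicate 2. DESeq2, limma-trend and total-count scaling gave 0 calls, against 918 higher and 219 lower, 1375 and 970, and 1356 and 1265 at an unadjusted p under 0.05, where edgeR had 1894 and 828. Scaling on the profile flanks moved the median of all windows by -0.83 and gave 8 higher and 820 lower, and scaling on total counts moved it by -0.12. Without IgG replicate 1 there were 334 higher and 63 lower, without IgG replicate 2 there were 2 and 0, without the IgG input 0 and 0, without the NuMA input 4 and 0, and without NuMA replicates 1 and 2 in turn 47 and 41 lower.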

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

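Scaling on the metagene flanks, leaving out overlapping windows, leaving out an input and the 5-position window were chosen after the data were seen; the other alternatives were planned. The TSS ratio of NuMA over IgG stayed between 1.51 and 1.86 under all its alternatives. The exon ratio moved from 0.971 to 1.11 with the outermost flank bins as denominator; its doubled window was not run because it already spans every bin. Corrections for GC content, alone or with a replicate block, were not run for lack of a genome sequence. No alternative called a window in the direction opposite to that reported. The cause of the changes below was not tested.

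NuMA against IgG, 2640 higher and 3761 lower: at least 30 counts, 772 and 1819; DESeq2 test, 1634 and 2117; flank scaling, 7562 and 429; relative to own inputs, 199 and 405; above 1.5-fold, 1366 higher; leaving out 1 library, 596 to 2875 higher and 1445 to 2906 lower. Its 7 called lists became 0 with an estimated correlation. The fry test, of each list against no change and not against other promoters, called 3 lists here and 0 in each comparison with input.

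NuMA against input, 2960 higher and 2045 lower: total counts, 1852 and 3313; DESeq2 test, 1876 and 619; flank scaling, 1861 and 684; own input, 1865 and 1314; at least 30 counts, 3232 lower; pooled inputs, 3427 lower; leaving out 1 library, 1246 to 3182 higher and 956 to 2225 lower. Its 4 called lists became 0 with an estimated correlation (0 with fry).

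IgG against input, 41 higher and 11 lower: DESeq2 size factors, 62 and 19; total counts, DESeq2 test, limma-trend and own input, 0 and 0 each; replicate block, 265 and 30; flank scaling, 8 and 820; pooled inputs, 1 and 5; no filter 25, at least 30 counts 20, thinned counts 20 and no overlap 27 lower; leaving out 1 library, 0 to 334 higher and 0 to 63 lower. Its 14 called lists became 0 with an estimated correlation (0 with fry).

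No alternative reversed the direction of a named gene that passed, or the direction of a list that passed relative to other promoters. Flank scaling ended the zinc finger call in NuMA against IgG (adjusted p = 0.0535) and, in IgG against input, the calls of zinc finger (0.19) and single-strand break repair genes (0.0663). Over all lists and alternatives except fry 42 of 250 calls were lost and 13 gained; over all named genes 164 of 659 were lost and 12 gained. At this depth and with 2 libraries per group, 2% of simulated 2-fold and 58% of 4-fold changes were recovered for NuMA against IgG. That simulation made 63 calls, far fewer than the data, so its adjusted threshold was stricter and these shares do not describe the real fit.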

Other observations

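All families and chromosomes here, and all weighed tests except the position of NuMA signal in shared windows and the matching on input counts, were chosen after the results were seen.

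Genes sharing a symbol stem were also tested as families. In NuMA ChIP against IgG ChIP, the 148 tested odorant receptor promoters included 114 lower and none higher, with a median of -2.05 (camera adjusted p = 1.43e-17, but adjusted p = 0.794 with an estimated correlation, and a median of -0.70 on flank scaling). Chemokine genes of the CCL family were lower in 18 of 22 (median -2.23), beta-defensin genes in 16 of 22 (-1.83) and late cornified envelope genes in 11 of 17 (-1.73). Keratin genes fell in 25 of 46 with a median of -1.19 that turned to 0.09 on flank scaling, and keratin-associated protein genes in 28 of 80 with -0.88 that turned to 0.39. That scaling moves all windows by 1.30, and relative to the median of all windows the 2 families stood at -1.15 and -0.84 without it and at -1.17 and -0.87 with it. Frizzled receptor genes of the WNT pathway were higher in 8 of 10 (median 1.43), SOX genes in 7 of 15 with none lower (1.35) and NKX homeobox genes in 7 of 12 with 1 lower (1.13). Other developmental families did not pass: HOX genes alone had 7 of 23 higher and 2 lower (median 0.33, adjusted p = 0.12), TBX genes 4 of 12 higher and 3 lower (0.25, adjusted p = 0.598) and POU genes 7 of 14 higher and 3 lower (0.65, adjusted p = 0.503). The ZNF family, with 29 of 342 higher and 61 lower, did not pass either (median -0.07, turning to 1.22 on flank scaling, or -0.03 and -0.04 relative to all windows; adjusted p = 0.982). Of 158 families 7 were higher and 20 lower, and none passed with an estimated correlation (smallest adjusted p = 0.794 with an estimated correlation).

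Against input, SOX, NKX and FZD promoters were again higher, with medians of 1.87 and 1.88 for SOX and NKX, and BMP genes, encoding bone morphogenetic proteins, rose in 7 of 11 (1.38). Mitochondrial ribosomal MRPS genes fell in 9 of 20 (median -1.23), and cytosolic RPL genes in 15 of 33 (-1.34). HOX genes alone, 7 of 24 higher and 2 lower, did not pass (median 0.61, adjusted p = 0.0858). Of 180 families 6 were higher and 6 lower, and none passed with an estimated correlation (smallest adjusted p = 0.872 with an estimated correlation). Chromosome 18, gene-poor among human chromosomes, was the 1 chromosome of 23 called: 62 of its 231 tested promoters were higher and 8 lower against input (median 0.55, adjusted p = 0.00432, and adjusted p = 0.506 with an estimated correlation), and 53 of 221 were higher and 30 lower against IgG (median 0.52, adjusted p = 0.0495, and 0.646 with an estimated correlation).

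Developmental and immediate early promoters were higher in NuMA ChIP than in IgG ChIP, and the tables part the lists. For developmental regulators, window overlap is argued against because 0 of 33 members overlap another window. The list passed with the overlapping windows of other genes left out (adjusted p = 0.00065). Scaled on promoter counts, medians lay above input in IgG ChIP (0.47, not passing) and NuMA ChIP (1.23). On flank scaling the IgG median turned to -0.37 and the NuMA median was 1.53. Low IgG counts as the whole cause are therefore argued against by the NuMA median only. That NuMA call (adjusted p = 3.54e-06) was lost with an estimated correlation (0.573). On recovery of open chromatin, the median lay above 99.87% of random lists matched on input counts. Those lists draw unrelated windows, while the members had an estimated correlation of 0.304, so the percentile is overstated and cannot decide this. Input counts are also no direct measure of open chromatin. The immediate early median lay at 95.33%, so open chromatin cannot be told apart from NuMA signal there, because the value falls between the bounds set beforehand. Low IgG counts remain a candidate explanation for the immediate early list, which was lower in IgG than in input (adjusted p = 0.00016). Base composition was not tested, the calls did not hold with an estimated correlation, and no biological explanation was tested.

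Liver, blood, germ cell, olfactory receptor and zinc finger promoters were lower in NuMA ChIP than in IgG ChIP, with a median of -1.47 over 89 members, or -1.43 relative to all windows, though no call held when the correlation was estimated (adjusted p = 0.551 to 0.576 with an estimated correlation). The bootstrap intervals below resample members and not libraries, so they leave out the spread between libraries. IgG replicate 2 alone is argued against, since without it the median was -1.23 (bootstrap 95% interval -1.51 to -1.04) and 5 of the 5 lists were called lower, with the lone IgG library assumed to vary like the NuMA libraries, and 4 were without IgG replicate 1. A rise of IgG over input (median 0.71) as the whole cause would put NuMA ChIP at or above input. For the 89 members together the median there was -0.56 (bootstrap 95% interval -0.90 to -0.37, and a median of -0.27 on flank scaling). Because that interval holds no spread between libraries, it cannot decide this. Such a rise may account for single lists, since liver alone passed there (adjusted p = 0.014) and the intervals of the olfactory receptor, blood and zinc finger medians reached 0. A lower level of NuMA signal itself cannot be told apart from scaling on promoter counts, because flank scaling, which moves all windows by 1.30, left a median of -0.10 with an interval that reached 0 (-0.29 to 0). Relative to all windows the median on that scaling was -1.36. A change of scaling moves all windows by nearly the same amount, so this gap had to stay nearly the same and is no test of scaling. Flank scaling ended the zinc finger call (adjusted p = 0.0535, and 0.00929 without it). No biological explanation was tested.

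Windows that overlap another had fewer counts, with 87.9% of those sharing over 1000 bp left untested against 8.07% of those sharing none, and their median was -0.56 against -0.03. Reads in a pair of windows may have been left out of the counts: per base not shared, windows overlapping by 1000 to 1500 bp held 0.931 times the IgG input counts of the others. The lower NuMA fold may follow from signal near the TSS lying in the shared part, since the profile over the unshared part shifted the ratio by -0.15. That shift lies between the bounds set beforehand and below the -0.54 observed, so this cannot be told apart from other causes. No biological explanation was tested.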
